A study of Mus musculus with 2 samples.

How the data were processed

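Chromatin immunoprecipitation followed by sequencing was done with an antibody against H3K9ac, histone H3 acetylated at lysine 9, on mouse kidney taken on the day of birth. The series held 1 group with 2 biological replicates, per the labels: replicate 1 was made from the kidneys of 15 mice, and replicate 2 from a pool whose size was not stated. Both pools mixed males and females of a C57BL/6N-type strain, and both libraries were made with a size range of 300 to 500 bp, per the labels. The replicates are therefore separate pools of animals, and no second group was there to compare with.

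The authors deposited peak lists rather than reads. A list was given for each replicate, a list of all peaks was called on both replicates together, and a replicated list was derived from these 3, per the file lists deposited with the samples. Peaks were called from filtered alignments together with 2 further files of a kind that is not stated there, on the mouse build mm10. The aligner, the peak caller, the threshold and the rule that made a peak replicated were not given in the sources used here. Each deposited line held an interval, a score for display, a signal value, the −log10 p-value, the −log10 q-value and the position of the summit. The signal value, called the enrichment value below, is the authors' own value per peak, and its scale relative to a control is not stated. It was used to describe and rank peaks, in the rank correlation between the replicates, and in a permutation test between promoters of the X and the autosomes within the replicated list. The deposited score was not used. No read counts or control libraries were analysed here, so the sequencing depth behind the lists is unknown, and a missing peak can reflect depth as well as absence of the mark. A −log10 p-value just above 2 was the lowest in each of the deposited lists.

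Gene positions came from GENCODE release M21 and sequence from the GRCm38 assembly, which is the build called mm10. No chromosome had a peak that ran past its end in this assembly. A transcription start site (TSS) was taken from every annotated transcript of a gene. A promoter was called marked when a replicated peak overlapped the 1 kb either side of any TSS of the gene by at least 1 bp. The background was all 21911 protein-coding genes on chromosomes 1 to 19, X and Y. Peaks outside TSSs of protein-coding genes were placed in exons, introns or between genes by their summit, and distal peaks lay more than 2.5 kb from every annotated TSS of any gene type. A peak at a promoter shared by neighbouring genes marked each of them.

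Overlap between the replicates was counted with at least 1 bp in common on chromosomes 1 to 19 and X. Chance overlap came from 1000 seeded circular shifts of the intervals within their chromosomes, and the same shifts served for peaks at TSSs; these tests were one-sided and 0.001 was the smallest p-value they could give. For 28 gene lists, marked promoters were compared with those of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. An alternative drew 10000 random lists with the same numbers of genes per decile of promoter CpG observed/expected ratio, measured in the 500 bp either side of the TSS; the smallest two-sided p-value was 0.0002. High CpG promoters had a ratio of at least 0.6 and low ones a ratio below 0.4. Covered length was the number of base pairs covered by replicated peaks within 5 kb either side of the TSS with most coverage. It can sum separate peaks and peaks of neighbouring genes, so it is not the length of a single region. A list's median was compared with 10000 random lists of marked genes by a two-sided permutation test for lists with at least 5 marked genes. Promoters marked in only 1 replicate were compared between lists by Fisher's exact test. Motif shares used McNemar's exact test between the 200 bp around the summit and the 200 bp that started 1 kb to its right, with up to 20 shuffled versions of each motif as a control for base composition. Shares carry Wilson 95% intervals, which cover counting error only.

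Peaks and genes are not independent replicates, and neighbouring genes share peaks. The p-values therefore describe the lists in these 2 libraries and are not tests across animals. The gene lists, tests, thresholds and most alternatives were fixed before the data were examined. Genes were named by a rule fixed then: up to 4 marked members of each list with the highest enrichment value, up to 3 unmarked members in alphabetical order, the 10 broadest regions after joining replicated peaks within 500 bp, the 10 distal peaks of highest enrichment value, all Hox genes, and promoters of a list marked in 1 replicate alone when 5 or fewer. Strongest peaks at any place, gene families outside the lists, non-coding genes and genes on chromosome Y or contigs were chosen after the values were seen. So were list members said below to be named outside the rule.

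Each result was recomputed with some of the following alternatives, not with all of them. Overlap rules, TSS windows of 500 or 2500 bp and the TSS furthest 5' alone were used. Peak sets were those with a −log10 q-value of at least 2, the list of all peaks, each replicate alone and the 20000 peaks of lowest p-value per list. Without replicate 1 means below that the full replicate 2 list (62377 peaks) took the place of the replicated list (29293 peaks). Without replicate 2 means the same with the full replicate 1 list (60648 peaks). Such a change thus joins a longer, less strict list with the loss of a replicate. Limits of 0.75 and 0.25 for CpG classes, a 10 kb flank for covered length and other motif windows were also used. Restriction to replicated peaks that overlap both replicates, restriction to peaks at no other promoter, and CpG matching of covered length were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. The code was tested on simulated data. Peaks planted at 4960 promoters were recovered at 100% of them, and 2 independent random lists overlapped by 0.331%, against 0.376% after shifting. In 50 simulated runs with a list of 14 marked and 6 unmarked genes, that list was called in 50 runs, and 1 of 1350 random lists was called. In these runs peaks were planted at 4960 promoters besides random positions, fewer than the 13779 promoters marked in the data. The runs therefore do not give the power of the reported tests. In the data, 14 of 20 marked genes of the loop of Henle and distal tubule gave an adjusted p of 0.646 (Fisher's exact test). A planted motif was found in 300 of 300 sequences. A planted shift of a list median was called, with 0 of 19 random lists called.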

Results

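H3K9ac, an acetylation of histone H3 found mainly at active promoters and enhancers, was profiled in newborn mouse kidney, an organ that at birth still makes nephrons from progenitor cells. Replicate 1 held 60648 peaks covering 28.6 Mb and replicate 2 held 62377 peaks covering 32.5 Mb. The list called on both replicates together held 64993 peaks over 37.0 Mb, and the replicated list 29293 peaks over 28.1 Mb, or 1.03% of the assembled chromosomes. Replicated peaks were wider, with a median of 708 bp against 302 bp in the list of all peaks. A −log10 q-value of at least 2 was reached by 48.8% of replicate 1 peaks, 74.1% of replicate 2 peaks and 98.0% of replicated peaks. The depth of the libraries is unknown.

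The strongest replicated peaks were chosen for naming after their values were seen. The highest enrichment value, 51.6, belonged to a peak 14134 bp from the nearest protein-coding TSS, that of the chromatin remodeller Chd2 (chromosome 7, 73555964 to 73558634, mm10). This peak was not distal by the definition above, since the highest value among distal peaks was 29.3. An annotated TSS of another gene type therefore lay within the distance that defines distal peaks. Peaks over the TSSs of Ino80d, a subunit of a chromatin remodelling complex (47.6), Brpf3, a scaffold of histone acetyltransferase complexes (46.6), and Kmt5b, a histone H4 lysine methyltransferase (46.0), followed. Srsf6, a splicing factor (45.8), and the polyubiquitin gene Ubc (44.5) were also among the 10 highest.

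The first comparison asked how far the 2 pools gave the same peaks. Of 60639 replicate 1 peaks on chromosomes 1 to 19 and X, 30205 overlapped a replicate 2 peak (49.8%, 95% interval 49.4 to 50.2). In the other direction, 27855 of 62368 replicate 2 peaks were overlapped (44.7%, 44.3 to 45.1). Shifted positions gave means of 2.41% and 2.35% and at most 3.10% and 2.99%, so that both shares were above all 1000 shifts (p = 0.001, permutation test, the smallest possible). The shared bases made up 45.2% of the bases covered by either list. Overlap depended on the enrichment value: in the highest decile of each list 100% of peaks overlapped, and in the lowest decile 18.6% in replicate 1 and 16.0% in replicate 2. Across the 30205 overlapping pairs, the enrichment values of the replicates had a Spearman rho of 0.722, which rose to 0.919 over the 19533 pairs sharing 50% of both peaks. Overlap fell to 32.2% and 31.3% when 50% of both peaks had to be shared, and rose to 84.2% and 79.2% among the 20000 peaks of lowest p-value in each list. With a −log10 q-value of at least 2, overlap was 75.2% of replicate 1 peaks and 45.7% of replicate 2 peaks.

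**Figure D1:**
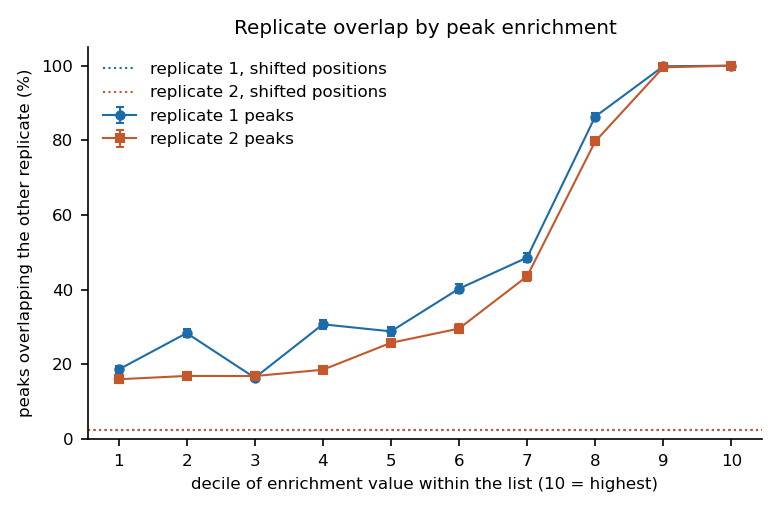
Share of peaks that overlapped the other replicate (vertical axis, percent) by decile of the authors' enrichment value within each list (horizontal axis, 10 the highest), with Wilson 95% intervals; dotted lines give the mean after shifting positions. Overlap rose from 18.6% and 16.0% in the lowest decile to 100% in the highest, while shifted positions stayed at 2.41% and 2.35%.

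All 29293 replicated peaks were unchanged peaks of the list of all peaks, of which 45.1% were kept. Every one of the 24764 peaks that overlapped both replicates by 50% of either peak was kept. Of the replicated peaks, 24929 (85.1%) overlapped both replicate lists by 1 bp, so that 4364 (14.9%) did not. Peaks left out were weaker and narrower, with a median enrichment value of 2.78 and a width of 224 bp, against 5.02 and 708 bp for those kept. Among the 35700 peaks left out, 16908 (47.4%) overlapped replicate 2 alone and 8770 (24.6%) replicate 1 alone.

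Replicated peaks lay mostly at promoters. Of 29284 replicated peaks on chromosomes 1 to 19 and X, 18242 (62.3%, 61.7 to 62.8) lay within 1 kb of a TSS of a protein-coding gene, against a mean of 5.60% and a maximum of 6.89% for shifted positions (p = 0.001, permutation test, the smallest possible), a ratio of 11.1. Of all these peaks, 3.69% lay outside TSSs with their summit in exons, 18.0% in introns and 16.0% between genes. Among these 11042 peaks outside TSSs of protein-coding genes, 1148 lay within 1 kb of a TSS of another gene type, and 7233 were distal. Within the replicated list the median enrichment value was 8.69 at TSSs, 3.45 in introns and 3.81 between genes. The peaks that were not kept as replicated were placed differently, with 18.5% at a TSS and 47.5% in introns. In each replicate list alone the TSS share was 40.4% (replicate 1) and 40.6% (replicate 2), and counting only the TSS furthest 5' gave 49.9%.

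A replicated peak marked the promoters of 13779 of 21911 protein-coding genes (62.9%, 62.2 to 63.5). All 15 genes of the early nephron, the vesicle and S-shaped body that follow the progenitor state, were marked, as were 19 of 20 podocyte genes, which serve the filtration barrier of the glomerulus, and 19 of 20 endothelial genes. Each of these 3 lists was marked more often than the other genes (adjusted p = 0.00286, Fisher's exact test). Among early nephron genes, the highest values were at Sox4 (16.9), Pax8, a transcription factor needed for kidney formation (16.4), Jag1, a Notch ligand (14.4), and Ccnd1, cyclin D1 (12.2). Among podocyte genes they were at Cd2ap, an adaptor of the slit diaphragm (25), the growth factor Vegfa (24.6), Foxc2 (23.0) and Actn4 (22.8). The median over marked podocyte genes was 9.53, and the lowest values were at Nphs2 (3.49) and Ptpro (4.79), named outside the rule. Nphs1, which encodes nephrin, was the podocyte gene without a replicated peak, although each replicate list had a peak there, of value 3.74 in replicate 1 and 2.58 in replicate 2. Fli1 (15.2), Gja5 (13), Eng (11.5) and Cldn5 (10.7) had the highest values of the endothelial genes. Vwf lacked a replicated peak, with peaks of 3.28 and 3.44 in the replicate lists. These are rankings within each list. Medians over marked early nephron, podocyte and endothelial genes were 9.92, 9.53 and 6.90. Among all marked promoters these medians lay at percentiles 36.8, 34.8 and 21.4. Ccnd1, Eng and Cldn5 lay at percentiles 48.4, 45.1 and 41.1. The peak at Gja5 also reached the promoter of Gpr89. When random lists were matched on promoter CpG content, endothelium kept its call (adjusted p = 0.000933, permutation test), and early nephron (0.345) and podocyte (0.802) did not.

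Nephron progenitor genes were marked in 14 of 16 cases (87.5%, 64.0 to 96.5), which did not pass the adjusted test (adjusted p = 0.0739, Fisher's exact test). The highest values of this list were at Sall1, a zinc finger factor of progenitors (27.2), Bmp7 (14.6), Pax2 (13.9) and Uncx (12.8). The median over its marked genes was 8.24, at a percentile between 26.9 and 29.3 among all marked promoters. Lower values, at genes named outside the rule, were those of Six2 (6.33), Cited1 (4.79), Osr1 (3.55), Six1 (3.33) and Meox1 (3.26). Crym had a peak in replicate 2 alone and Dapl1 in replicate 1 alone; Meox1, which was marked, had a peak at its promoter in the replicate 2 list alone. The replicate 1 list alone marked 14 of these genes and the replicate 2 list alone 15. With CpG matching 13.4 marked genes were expected (odds ratio 1.29 against 3.43, adjusted p = 1.00, permutation test). Even full marking would have given p = 0.0318 before adjustment (permutation test), and the 0.0258 of the proximal tubule list adjusted to 0.0657. Nephron progenitor genes could therefore not have passed with CpG matching. Of 25 genes of the ureteric bud and collecting duct, the branching tube that becomes the urine-collecting system, 20 were marked (adjusted p = 0.104, Fisher's exact test). Hoxb7 (28.6, a peak shared with Hoxb4, Hoxb5, Hoxb6 and Hoxb8), Etv5 (20.5), Emx2 (19.8) and Grhl2 (13.6) had the highest values. Avpr2, the vasopressin receptor, Calb1 and Elf5 were unmarked. The median over the marked genes of this list was 7.85. It was 7.51, at percentile 24.5 among all marked promoters, for the stromal list given next. Of 23 stromal and mural genes, 19 were marked (adjusted p = 0.0650, Fisher's exact test), led by Meis2 (25.7), Meis1 (20.9), Tcf21 (20.2) and Pbx1 (13.4), with Dcn, Lum and Postn unmarked. With CpG matching the stromal list passed the test (adjusted p = 0.0184, permutation test), as it did without replicate 2 (0.00264, Fisher's exact test).

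Genes of mature tubules did not pass the test. Of 26 proximal tubule genes, 14 were marked (53.8%, adjusted p = 0.432, Fisher's exact test). They included the bicarbonate transporter Slc4a4 (11.4), the regulator Hnf1a (10.7), the fatty acid transporter Slc27a2 (8.05) and the endocytic receptor Lrp2 (7.48). Its partner Cubn, Cyp4b1 and Kap, an androgen-regulated kidney protein, were unmarked. Of 20 genes of the loop of Henle and distal tubule, 14 were marked (70.0%, adjusted p = 0.646, Fisher's exact test). Hnf1b (19.2), Wnk1, a kinase that regulates salt transport (17.2), Tfap2b (9.06) and Sim2 (6.14) led this list. The median over its marked genes was 4.22, at percentile 7.28 among all marked promoters, and that of the proximal tubule list was 5.43. Kcnj1, the potassium channel of the thick ascending limb, lacked a replicated peak, with peaks of 3.32 and 3.53 in the replicate lists, and Kcnj16 and Pvalb had a peak in replicate 2 alone. The remaining unmarked members, named outside the rule, were Slc12a3, Slc12a1 and Umod. Slc12a3 had peaks of 2.99 and 4.02 in the replicate lists, and Slc12a1 and Umod had no promoter peak in either. The full replicate 2 list, longer than the replicated list, marked 18 of the 20 genes of the loop and distal tubule, and the full replicate 1 list 16. With CpG matching, 9.23 marked proximal tubule genes were expected, which turned the odds ratio from 0.684 to 2.06 (adjusted p = 0.0657, permutation test), and 10.6 of the loop and distal tubule (odds ratio 1.99, adjusted p = 0.122).

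Markers of immune and erythroid cells and of other tissues were marked in few cases. The marked share was 2 of 20 immune genes (adjusted p = 5.65e-06, Fisher's exact test), 2 of 20 hepatocyte genes (5.65e-06), 3 of 14 erythroid genes (0.00507), 2 of 15 adrenal genes (0.000266), 6 of 20 neuronal genes (0.00572) and 7 of 20 heart and skeletal muscle genes (0.0228). It was 3 of 15 for pancreas and 1 of 10 for lung and thyroid (0.00178 each), and 2 of 15 for epidermis and for germ cells (0.000266 each). The marked immune genes were Coro1a (4.99) and Csf1r, the receptor of macrophage colony-stimulating factor (3.38), while Adgre1, Cd19 and Cd3e were unmarked. Klf1 (14), Tal1 (8.63) and Gypa (5.05) were the marked erythroid genes, with Alas2, Epb42 and Ermap unmarked. Cebpa (4.13) and Trf (3.20) were the marked hepatocyte genes, with Afp, Ahsg and Alb unmarked. The steroidogenic gene Star (2.67) and Phox2a (9.40) were marked, and Akr1b7, Chga and Cyp11a1 were not. Among neuronal genes, Slc17a7 (7.48), Grin1 (4.75), Gabra1 (4.69) and Gad1 (3.84) had the highest values, and Dcx, Gad2 and Nefl were unmarked. Muscle genes with the highest values were Mylpf (21.9), Ryr2 (6.71), Des (5.63) and Ckm (4.28), with Acta1, Actc1 and Myf5 unmarked. The peaks at Mylpf and Ckm also reached the promoters of Tbc1d10b and Klc3. Nkx6-1 (3.38), Cela1 and Nkx2-2 (3.26 each) were marked in the pancreas list, and Amy2a5, Cela2a and Cpa1 were not. Tshr (6.22), whose peak also reached Cep128, was the marked gene for lung and thyroid, and Nkx2-1, Scgb1a1 and Scgb3a2 were unmarked. Krt10 (10.2) and Krt1 (7.29) were marked in the epidermis list, with Dsg1a, Dsg3 and Flg unmarked. Dazl (9.59) and Zpbp (13.6, a peak shared with Spata48) were marked in the germ cell list, with Acrv1, Ddx4 and Mael unmarked. With CpG matching, the adrenal (adjusted p = 0.0330, permutation test), neuronal (0.000933), pancreas (0.0324) and germ cell (0.000933) lists kept their calls, with odds ratios of 0.326, 0.169, 0.309 and 0.128. The calls of the immune (odds ratio 0.584, adjusted p = 0.802, permutation test), hepatocyte (0.315, 0.0957), erythroid (1.13, 1.00), muscle (0.785, 0.861), lung and thyroid (0.335, 0.192) and epidermis (0.459, 0.345) lists ended. Without replicate 2 the adrenal (0.0697), muscle (0.175) and lung and thyroid (0.0517) lists lost their call in Fisher's exact test, and the neuronal list lost its call when only peaks at no other promoter were counted (0.0866). The single replicate lists marked as many of these genes or more: 4 (replicate 1) and 5 (replicate 2) immune genes, 3 and 6 hepatocyte, 5 and 3 erythroid, 6 and 4 adrenal, 7 and 6 neuronal, 10 and 8 muscle, 4 and 3 pancreas, 3 and 2 lung and thyroid, 4 and 3 epidermis, and 3 and 4 germ cell genes.

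Cell cycle, ribosomal protein, respiratory chain and proteasome genes were nearly all marked. The 20 cell cycle genes were all marked (adjusted p = 0.000266, Fisher's exact test), with the highest values at Aurka, a mitotic kinase (19.6), the replication helicase genes Mcm4 (17.1) and Mcm5 (13.3), and the proliferation marker Mki67 (15.7). The peaks at Aurka and Mcm4 also reached Cstf1 and Prkdc. Of 83 ribosomal protein genes 80 were marked (adjusted p = 3.30e-12, Fisher's exact test), with Rps19 (42.9), Rpl23 (36.4), Rpl6 (34.5) and Rps6 (33.0) highest. The 3 unmarked members, Rpl10l, Rpl39l and Rpl3l, are paralogs named as ribosomal-protein-like. Of 93 genes of the respiratory chain and ATP synthase 88 were marked (adjusted p = 5.87e-12, Fisher's exact test), led by Atp5g3 (36.8), Atp5a1 (36.6), Atp5j (33.6) and Atp5c1 (30.3). The peaks at Atp5a1, Atp5j and Atp5c1 also reached Haus1, Gabpa and Kin. Cox6a2, Cox7b2 and Cox8b were unmarked. Of 40 proteasome genes 38 were marked (adjusted p = 1.31e-05, Fisher's exact test), with Psmd3 (32.0), Psma3 (28.1), Psmd6 (26.5) and Psmc1 (26.3) highest, and without Psma8, a testis subunit, and Psmb11, a thymus subunit. With CpG matching, the respiratory chain list kept its call (adjusted p = 0.0266, permutation test), and the cell cycle (0.861), ribosomal (0.861) and proteasome (0.714) lists did not. All cell cycle genes being marked, against 18.98 expected, this list could not have passed that test (p = 0.667 with full marking, permutation test). Nor could the proteasome list, where full marking would have given p = 0.0252 before adjustment (permutation test). The respiratory chain list lost its call when only peaks at no other promoter were counted (0.190, Fisher's exact test).

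Large gene families went in different directions. None of 1134 olfactory receptor genes was marked, among them Olfr1, Olfr10 and Olfr1000; the 95% interval reached up to 0.338%. The single replicate lists marked 6 (replicate 1) and 3 (replicate 2) of them. Of 330 vomeronasal receptor genes 1 was marked (adjusted p = 1.00e-140, Fisher's exact test), Vmn1r4, whose peak also reached Nt5c3; Vmn1r1, Vmn1r10 and Vmn1r100 were unmarked. C2H2 zinc finger genes of the Zfp series were marked in 305 of 365 cases (adjusted p = 2.48e-17, Fisher's exact test), with Zfp618 (40.1), Zfp91 (38.7, a peak shared with Lpxn), Zfp236 (37.4) and Zfp326 (35.5) highest and Zfp345, Zfp352 and Zfp42 unmarked. Solute carrier genes were marked in 251 of 361 cases (69.5%, 64.6 to 74.1, adjusted p = 0.0111, Fisher's exact test), against 62.8% of other genes. These other genes include the receptors, which lower the share that every other list was compared with. Of all genes outside the olfactory receptors 66.3% were marked, which lies inside the interval of the solute carriers. Slc39a10, a zinc transporter (38.2), Slc38a2, an amino acid transporter (33.1), Slc10a7 (32.2, shared with Rbmxl1) and Slc35d1 (32.0) were highest, and the bile acid transporters Slc10a1 and Slc10a2 were unmarked, as was Slc10a4. Imprinted genes were marked in 14 of 16 cases (adjusted p = 0.0739, Fisher's exact test), led by Gnas (33.1), Grb10 (19.5), Igf2r (14.7) and Impact (14.6), with Magel2 and Ndn unmarked; without replicate 1 the adjusted p was 0.0200. With CpG matching their odds ratio fell from 3.43 to 1.05 (adjusted p = 1.00, permutation test). Full marking would have given p = 0.0266 before adjustment (permutation test), so imprinted genes could not have passed either. With CpG matching the receptor families and the Zfp genes kept their calls (adjusted p = 0.000933 each, permutation test), and the solute carriers did not (0.925). In all, 10 of 28 lists were marked more often and 12 less often than other genes, and 4 and 6 with CpG matching.

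**Figure D2:**
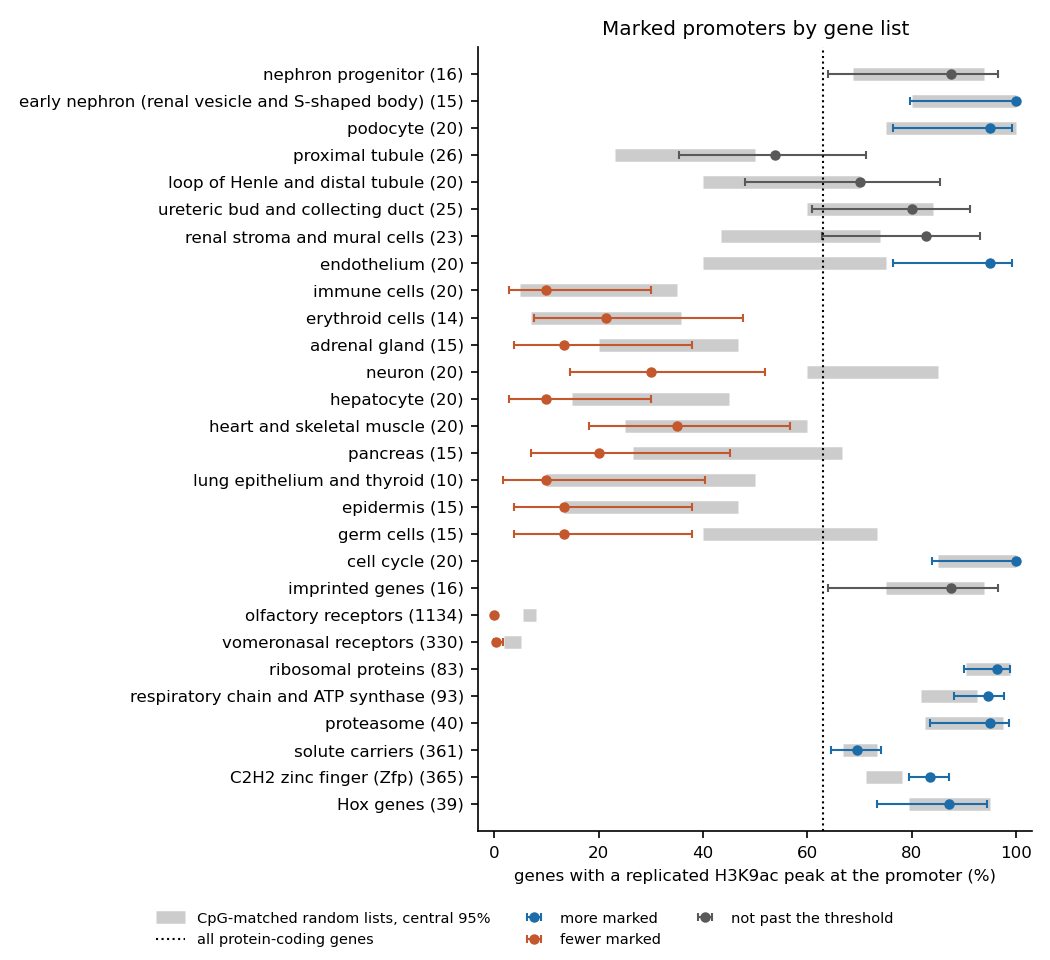
Share of genes with a replicated H3K9ac peak within 1 kb of a TSS (horizontal axis, percent) for each gene list, with the number of genes in brackets and Wilson 95% intervals; grey bars span the central 95% of random lists matched on promoter CpG content, and the dotted line is the share among all protein-coding genes, 62.9%. Endothelium (95%) and Zfp genes (83.6%) lay above their grey bars, and neuron (30.0%) and germ cells (13.3%) lay below theirs.

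Promoter sequence separated marked from unmarked genes strongly. High CpG promoters were marked in 10898 of 11514 genes (94.7%), intermediate ones in 2046 of 2936 (69.7%) and low CpG promoters in 835 of 7461 (11.2%). The odds ratio between high and low CpG promoters was 140, with a p-value below what double precision can hold in Fisher's exact test.

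On the X chromosome 402 of 948 promoters (42.4%) were marked, against 13373 of 20780 (64.4%) on the autosomes, an odds ratio of 0.408 (p = 5.35e-41, Fisher's exact test, two-sided). The gap held within each CpG class. Among high CpG promoters 85.4% on the X and 94.9% on the autosomes were marked (odds ratio 0.314, p = 9.69e-10, Fisher's exact test). Intermediate promoters gave 57.6% and 71% (0.556, p = 9.38e-05, Fisher's exact test), and low CpG promoters 6.09% and 11.8% (0.486, p = 0.000111). The transcription factor genes Sox3, Zic3 and Pou3f4, chosen after the values were seen, were among the 44 unmarked high CpG genes of the X.

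Covered length around the TSS was greater than at other marked genes for the early nephron, nephron progenitor, Hox and ribosomal protein lists. Around the 13779 marked promoters the median covered length within 5 kb either side was 1741 bp. It was 4106 bp for the 15 early nephron genes (adjusted p = 0.0012, permutation test), where random lists had a median of 1750 bp, and 3340 bp for the 14 marked nephron progenitor genes (0.0018). Pax2 had 8691 bp, Sall1 7752 bp, Ccnd1 5743 bp and Uncx 5718 bp covered. Hox genes had 8473.5 bp (0.0012), although neighbouring Hox genes share regions, and ribosomal protein genes 2577 bp (0.0012). Covered length was shorter for marked neuronal genes, at 739 bp over 6 genes (adjusted p = 0.0162, permutation test), for 7 heart and muscle genes (774 bp, 0.0189), for solute carriers (1500 bp, 0.00288) and for Zfp genes (1571 bp, 0.0189). The medians of podocyte (2060 bp), proximal tubule (1543 bp), loop and distal tubule (1463 bp), ureteric bud and collecting duct (2392 bp), stroma (2175 bp), endothelium (1855 bp), cell cycle (2188 bp), imprinted (1615.5 bp), respiratory chain (1951 bp) and proteasome genes (1743.5 bp) did not pass the test, with adjusted p from 0.054 to 0.986. Without replicate 1 the nephron progenitor median was 2452 bp (0.0709) and the neuronal median 820.5 bp (0.0587). Without replicate 2 the Zfp median was 1341 bp (0.0519) and the neuronal median 293 bp. Matching on CpG content ended the heart and muscle call (adjusted p = 0.144, permutation test), with a median 0.564 of the random one against 0.445 before, and the Zfp call (0.841), with 0.987 against 0.902.

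The broadest joined regions lay in Hox clusters. A region of 57.9 kb on chromosome 11 (96277167 to 96335088) held 10 replicated peaks and the TSSs of Hoxb3 to Hoxb8, and one of 34.3 kb on chromosome 6 (52207232 to 52241548) held TSSs of Hoxa3, Hoxa6, Hoxa7, Hoxa9 and Hoxa10. Next came 25.7 kb at Nr2f2, which encodes the nuclear receptor COUP-TFII (chromosome 7, 70345693 to 70371393), 17.2 kb at Meis2 (chromosome 2, 116055750 to 116072957) and 16.0 kb at Tbx2 (chromosome 11, 85829129 to 85845082). Regions of 15.0 kb at Hoxc9, 14.9 kb at Hoxd9 and Hoxd10, 11.8 kb at Tnrc18, 11.3 kb at Zfp503 and 10.4 kb at the histone methyltransferase gene Setd1b completed the 10 broadest.

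Hox genes pattern the body axis, and group 11 acts in the embryonic kidney. They were compared by paralog group. All 33 genes of groups 1 to 11 were marked, and 1 of 6 genes of groups 12 and 13 (p = 1.04e-05, Fisher's exact test, two-sided). The highest values were at Hoxd9 and Hoxd10, which share a peak (36.1), Hoxd8 (35.7) and Hoxb2 (30.9). Hoxa11 (20.9), Hoxc11 (11.7) and Hoxd11 (28.0) were the marked genes of group 11. Hoxd13 (4.22) was the marked gene of the posterior groups, with 397 bp covered. Hoxa13 and Hoxd12 had a peak in the replicate 1 list alone (4.11 and 3.35), and Hoxb13, Hoxc12 and Hoxc13 in neither. By cluster, 10 of 11 genes were marked in Hoxa, 9 of 10 in Hoxb, 7 of 9 in Hoxc and 8 of 9 in Hoxd. As a list, Hox genes were marked more often than other genes (34 of 39, adjusted p = 0.00242, Fisher's exact test), which was lost with CpG matching (adjusted p = 1.00, permutation test) and when only peaks at no other promoter were counted (0.167, Fisher's exact test). In the list of all peaks, and without replicate 2, 3 of the 6 posterior genes were marked (p = 0.00219, Fisher's exact test).

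**Figure D3:**
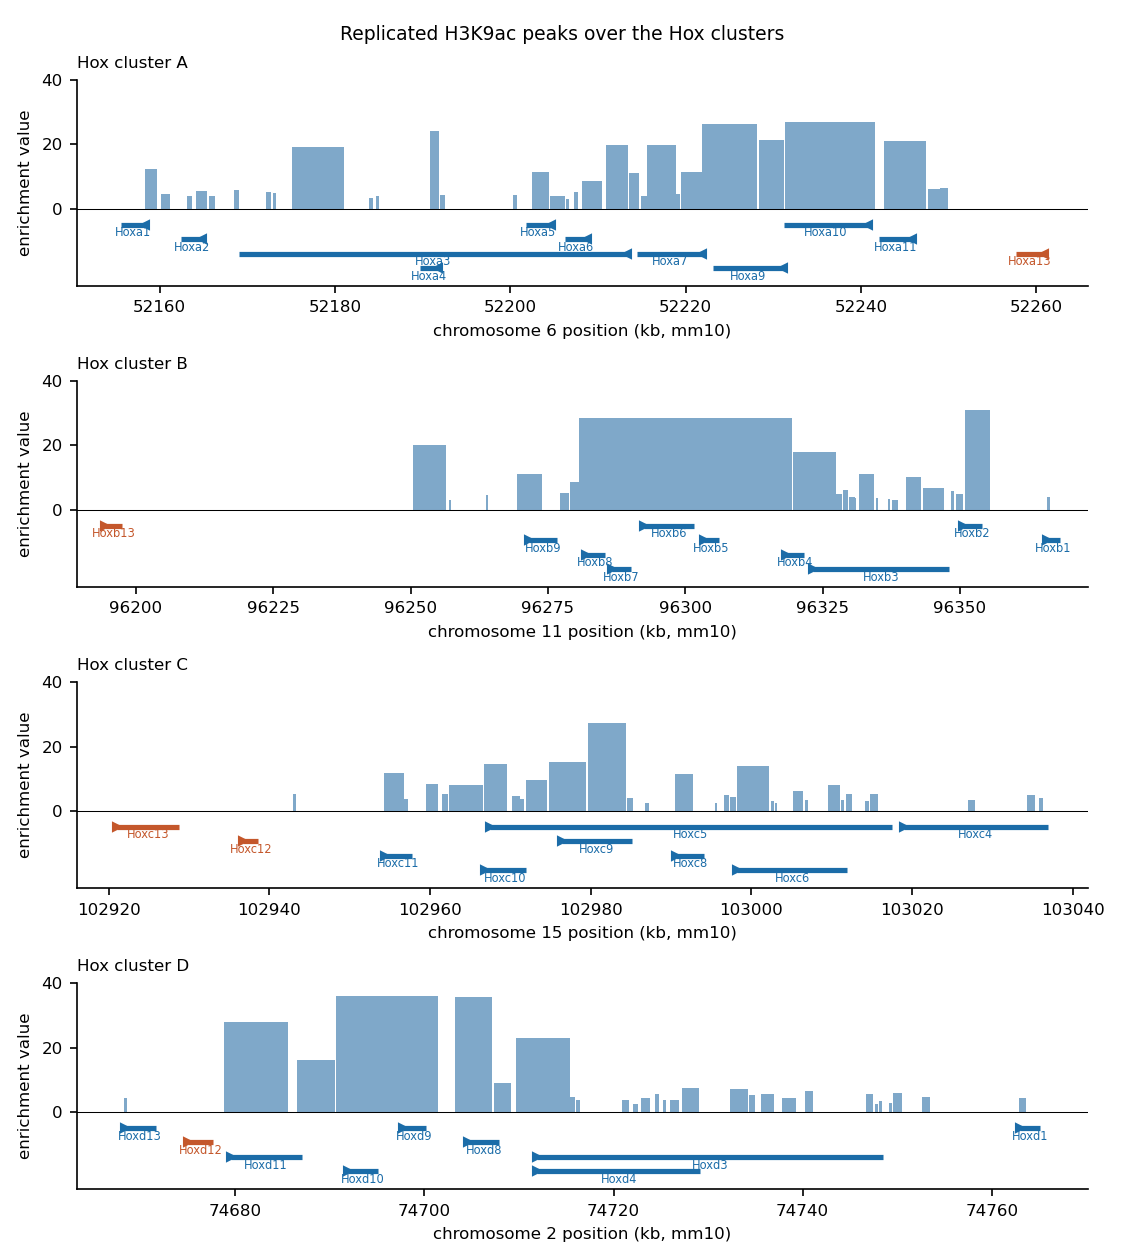
Replicated H3K9ac peaks over the Hox clusters A to D (mm10 positions in kb, horizontal axis), drawn as bars from start to end with the authors' enrichment value as height (vertical axis); genes are drawn below with an arrowhead at the TSS, marked genes in blue and unmarked genes in orange. Peaks are dense from Hoxa3 to Hoxa11, over Hoxb3 to Hoxb8 and from Hoxd11 to Hoxd8, and Hoxa13, Hoxb13, Hoxc12, Hoxc13 and Hoxd12 carry no replicated peak at the promoter.

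Among distal peaks, over 2.5 kb from every annotated TSS of any gene type, the one of highest value lay 61.7 kb from the TSS of Ppara, the nearest protein-coding gene (chromosome 15, 85669696 to 85673287, intergenic, value 29.3). It was followed by a peak within the Hoxc9 gene (chromosome 15, 102979645 to 102984355, 27.2), one 66.9 kb from Spag6 (chromosome 2, 18765963 to 18767726, 26.7) and one in an intron of Prdm2 (chromosome 4, 143160827 to 143162232, 26.7). A peak 29.6 kb from Pax2, between genes, reached 24.2 (chromosome 19, 44725835 to 44726478). The other 5 of the 10 highest had Zfp869 (24.2), Pum2 (22.4), Arhgap32 (22.1), Nufip1 (21.7) and Tcf12 (20.6) as nearest genes, at distances of 5.28 to 82.7 kb. Each of these 10 peaks overlapped a peak in both replicate lists.

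Sequence motifs at the 7233 distal summits were compared with flanking sequence 1 kb away. The KLF/SP motif GGGCGGGG was found at 4.24% of summits and 1.41% of flanks (ratio 3, adjusted p = 1.84e-24, McNemar's exact test). This ratio lay above the 6 shuffled versions, which reached 2.76. With so few versions, and the highest close to the motif's own ratio, base composition is only weakly controlled for this motif. The TFAP2 motif GCCNNNGGC (12.1% against 5.83%, adjusted p = 2.49e-39, McNemar's exact test) and the WT1/EGR motif GCGGGGGCG (0.622% against 0.0968%, adjusted p = 2.32e-07) were also more frequent, within the range of shuffled versions. ETS (adjusted p = 0.0397, McNemar's exact test), PAX (0.0397) and NFI (0.0454) motifs were more frequent by 1.97, 1.64 and 1.61 times, also within that range. Fewer summits than flanks had the motifs of HNF1 (0.359% against 0.719%, adjusted p = 0.0124, McNemar's exact test), HOX group 9-11 (3.14% against 5.79%, 3.15e-14), RUNX (2.82% against 5.27%, 3.32e-13), ESRR (0.332% against 0.622%, 0.0386) and NFY (15.5% against 21.3%, 2.55e-18), all within the range of their shuffled versions. Summits had 55.2% G and C and flanks 47.8%. Motifs of HNF4, AP-1, CTCF, TEAD, GRHL, FOX, the family SIX1 to SIX6, NRF1 and SOX did not pass the test. FOX (ratio 0.915, shuffled versions at most 0.880) and SOX (1.01, at most 0.952) nevertheless lay above every shuffled version. Without replicate 1 the ratios of KLF/SP and WT1/EGR were 1.84 and 2.76, and without replicate 2 they were 1.78 and 2.31. With either replicate left out, HNF1 (adjusted p = 0.0947 and 0.0849, McNemar's exact test) and ESRR (0.0933 and 0.0849) lost their calls, as did ETS without replicate 2 (0.399). Without replicate 1 or 2 the HNF1 ratio was 0.806 and 0.807, and with 500 bp windows it turned to 1.09.

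Promoters that only 1 replicate list marked were few, with 13729 marked in both, 585 in replicate 1 alone and 665 in replicate 2 alone (8.35% of promoters marked in any). For the proximal tubule list these were Keg1, Miox, Slc13a3 and Slc5a2 in replicate 1 and Cubn, Slc3a1 and Slc5a12 in replicate 2. For stroma they were Dcn, Lum and Ren1 in replicate 1, and for the adrenal list Cyp11a1, Dbh and Th in replicate 1 and Pnmt in replicate 2. Hepatocyte genes were Afp, Apoa1 and Serpinc1 in replicate 2, and erythroid genes Epb42 and Slc4a1 in replicate 1. Of the 5 lists with enough such genes to test, 0 passed the threshold. Zfp genes had the lowest p-value, with 1 promoter in replicate 1 alone and 10 in replicate 2 alone (p = 0.0131, adjusted p = 0.0657, Fisher's exact test), which passed the threshold with a 2500 bp window (adjusted p = 0.0460).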

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

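Replicated peaks outside chromosomes 1 to 19 and X took no part in the overlap of the replicates given above, and were looked at after the other results were seen. There were 4 on chromosome Y and 5 on contigs not placed in a chromosome. The 4 peaks on chromosome Y lay at the promoters of Kdm5d (value 4.22), Eif2s3y (4.22), Uty (5.75) and Ddx3y (5.18), genes whose X-linked relatives are expressed widely; both pools held males, per the labels. On the contigs, peaks lay at the promoters of Vamp7 (6.33) and Tmlhe (10.5), on a contig assigned to the X, and at CAAA01118383.1 (15.5) and AC149090.1 (2.22), with a further peak of 4.03 away from genes.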

How the results depend on the processing

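Of 619 comparisons of a reported value with an alternative, 447 on the main results and 84 on single motifs kept their side of the threshold, or moved less than the spread. In 4 and 19 of these a ratio without a call crossed 1. The 4 were proximal tubule odds ratios, 0.684 in the main result. They were 1.29 in the list of all peaks, 2.06 with CpG matching, 1.08 for peaks at no other promoter and 1.16 without replicate 2. Without replicate 1 the ratio stayed below 1, at 0.962. Among motifs 7 lost and 3 gained a call. Those on peaks overlapping both replicates, peaks at no other promoter and CpG matching of covered length were chosen after the results were seen. The depth of the libraries is unknown, so no result could be tied to it, and the cause of the shifts below was not tested unless the alternative itself lowers the number of peaks or genes. Replicate overlap (49.8% and 44.7%) became 32.2% and 31.3% with 50% of both peaks shared, 36.0% and 35.0% with summits within 200 bp, 75.2% and 45.7% at a −log10 q-value of at least 2, and 84.2% and 79.2% for the 20000 peaks of lowest p-value. Rho (0.722) was 0.919 with 50% of both peaks shared, 0.734 on −log10 p and 0.757 at the q limit, where 58.7% of all peaks were kept as replicated. The TSS share (62.3%) was 38.2% in the list of all peaks, 40.4% to 40.6% leaving out either replicate, 63.1% at the q limit, 58.0% and 70.3% with windows of 500 and 2500 bp, 49.9% with the TSS furthest 5', and 67.8% for peaks overlapping both replicates. At the q limit promoters in replicate 1 alone fell from 585 to 258 and those in replicate 2 alone rose from 665 to 913.

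With CpG-matched lists 4 lists were above and 6 below chance, against 10 and 12. Odds ratios without a call there were 4.40 (early nephron), 1.956 (podocyte), 3.20 (cell cycle), 1.40 (ribosomal), 1.82 (proteasome), 0.584 (immune), 0.315 (hepatocyte), 0.785 (muscle), 0.335 (lung and thyroid) and 0.459 (epidermis), and they turned to 1.13 (erythroid), 0.974 (solute carriers) and 0.955 (Hox); stroma gained a call (3.10). Nephron progenitor (1.29) and imprinted genes (1.05) stayed without one, both at 3.43 before. Neither these lists nor the early nephron, podocyte, cell cycle and proteasome lists could have passed with CpG matching, even with full marking. Nephron progenitor genes gained a call in the list of all peaks (odds ratio 5.14), at the q limit (3.44) and with 500 bp (3.50). They also did with the TSS furthest 5' (3.99) and for peaks at no other promoter (5.39). No call was gained with 2500 bp or for peaks overlapping both replicates (2.38). Leaving out either replicate gave 3.08 to 5.40 for this list. Imprinted genes gained a call in the list of all peaks (5.14), at the q limit (3.44), with 500 bp (3.50), 2500 bp (5.83) and peaks overlapping both replicates (3.58). They did not with the TSS furthest 5' (1.11) or for peaks at no other promoter (1.5), and had 3.08 to 5.40 leaving out either replicate. Ureteric bud genes gained one in the list of all peaks (4.67), with the TSS furthest 5' (2.56) and for peaks at no other promoter (2.79), and stroma likewise (4.28, 2.98 and 3.13). Peaks at no other promoter ended the calls of neuron (0.416), respiratory chain (1.34) and Hox genes (1.63). Leaving out either replicate gave 1.95 to 3.87 for the loop and distal tubule, 2.26 to 7.97 for stroma, 0.204 to 0.363 for adrenal, 0.355 to 0.530 for muscle and 0.153 to 0.248 for lung and thyroid.

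Covered length, leaving out either replicate, was 2406 to 2452 bp for nephron progenitor, 293 to 820.5 bp for neuron and 1341 to 1515 bp for Zfp genes. Ureteric bud genes gained a call with peaks within 500 bp joined (2674 bp) and with CpG matching (2392 bp), and respiratory chain genes with 10 kb flanks (2328 bp); muscle (774 bp) and Zfp genes (1571 bp) lost theirs with CpG matching, which lowered the random medians from 1741 bp to 1372 and 1591 bp. For promoters in 1 replicate alone, 1 list passed with a 2500 bp window. Motif ratios turned with 500 bp windows for HNF1 (1.09), CTCF (2.48) and NRF1 (5.29). Leaving out either replicate, they were 1.05 to 1.12 for AP-1 and 1.10 to 1.12 for the SIX1 to SIX6 family motif. Each alternative chosen in advance was run, and the CpG class, X chromosome and Hox group results kept their calls in all of theirs.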

Other observations

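The gene families, non-coding genes, means without the member with most peaks and tests of explanation below were chosen after the main results were seen, and the results of the CpG comparisons and of the test within high CpG promoters of the X had been seen when their tests were chosen. Families of developmental regulators were marked in part. Of 9 Pax genes, Pax8, Pax2 and Pax6 were marked, and Pax1, Pax3, Pax4, Pax5, Pax7 and Pax9 were not. Six5, Six4, Six2 and Six1 were marked, and Six3 and Six6, factors of eye and forebrain, were not. Irx3, Irx5, Irx1 and Irx2 were marked of 6 Irx genes, and Gata6, Gata2, Gata3 and Gata5 of 6 Gata genes, while Gata1 and Gata4 were not. Of 19 Wnt genes 11 were marked, among them Wnt11, Wnt7b, Wnt4 and Wnt9b of the branching and tubule-forming kidney, and Wnt1, Wnt3a and Wnt8a were unmarked. None of the 7 Neurod and Neurog genes was marked, and of 14 Nkx genes Nkx3-1, Nkx6-1, Nkx2-2 and Nkx6-2 were. Of 8 Lhx genes, Lhx1, Lhx6, Lhx4, Lhx8 and Lhx2 were marked, and of 13 Tbx genes, Tbx2, Tbx3, Tbx6, Tbx18, Tbx22, Tbx1, Tbx15 and Tbx21, so that the marked members were not limited to genes known from kidney. Of 11 aquaporin genes, Aqp11, Aqp3, Aqp2, Aqp5 and Aqp1 were marked, and of 49 keratin genes 8 were, namely Krt8, Krt18, Krt7 and Krt19 of simple epithelia, Krt10 and Krt1 of epidermis, Krt222 and Krt80. Claudin genes were marked in 15 of 23 cases. These counts carry no test.

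Non-coding genes also carried the mark. A replicated peak away from every protein-coding TSS lay at the promoters of 445 of 5854 lincRNA genes (7.60%) and 193 of 2959 antisense genes (6.52%), against 71 of 9940 processed pseudogenes (0.714%). The highest value among these lincRNA and antisense genes was at 6720427I07Rik (31.1), and Malat1 (23.5), Snhg6 (22.7), Mir17hg (22.3) and Neat1 (12.3) were marked. Among imprinted or X-inactivation RNAs, Airn (9.01), Kcnq1ot1 (6.55), Xist (4.36), H19 (3.91) and Meg3 (3.84) were marked, and Rian and Mirg were not, nor were Hotair and Hottip of the Hox clusters.

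Distal replicated peaks within 100 kb of the TSS were counted for marked genes of the 7 kidney lists, with the hypothesis that they gather near kidney genes. Wnt7b had 19 such peaks, Col1a1 11, Pax2 10, and Actn4 and Synpo 9 each. The median over 115 genes was 1, against 0 in random marked genes matched on the number of coding genes nearby (p = 0.373, permutation test), so the hypothesis was not borne out on the measure written in advance, which is coarse for such low counts. By list the median was higher for ureteric bud and collecting duct genes (2.5 against 0.5, adjusted p = 0.0096 over 12 groups, permutation test), and early nephron genes had 2 against 0 (adjusted p = 0.0504). The mean, a second measure not chosen in advance, was 2.22 against 1.13 (95% of random means between 0.809 and 1.51, p = 0.0002, permutation test, the smallest possible), with adjusted p over the 12 groups of 0.0024, and 2.07 against 1.04 (adjusted p = 0.0024) when the gene with most peaks, Wnt7b, was left out and each random list lost its own. By list the mean passed for nephron progenitor (2.57 against 0.953, adjusted p = 0.0414, permutation test), podocyte (2.47 against 0.974, 0.0384) and ureteric bud and collecting duct genes (3.10 against 1.26, 0.0192). These 3 also passed when the gene with most peaks was taken from the list and from each random list, at 2 against 0.625 without Pax2 (adjusted p = 0.012, permutation test), 2.11 against 0.693 without Actn4 (0.0072) and 2.26 against 0.949 without Wnt7b (0.012), and early nephron genes then passed too, at 2.07 against 0.611 without Pax8 (0.012). The mean over all members did not pass for early nephron (adjusted p = 0.0696, permutation test), stroma (0.0748), endothelium (0.131), proximal tubule (0.788) or loop and distal tubule genes (0.975).

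Early nephron, podocyte, endothelial and other lists were marked more often. Markers of immune and erythroid cells and of other tissues were marked less often. Promoter CpG content may account for part of this. It does not account for all of the difference for endothelium (adjusted p = 0.000933 against CpG-matched lists, permutation test) or for neuron (adjusted p = 0.000933). The same held for the immune, erythroid, hepatocyte, muscle, lung and epidermis lists as 1 set. There 17 of 99 genes were marked and 27.3 expected (95% of random lists between 21 and 34, p = 0.0042, permutation test). The set joined lists that had lost their own call under CpG matching, so it does not speak for each list alone. Marked and expected counts were 2 and 5.8 for hepatocyte, 1 and 3.02 for lung and thyroid and 2 and 4.10 for epidermis genes. They lay closer for immune (2 and 3.45), muscle (7 and 8.20) and erythroid genes (3 and 2.68). Early nephron (p = 0.189, permutation test) and podocyte (p = 0.573) cannot be told apart from CpG content, because even full marking would have given p = 0.183 and 0.116. No biological explanation was tested, since the series has 1 group.

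The lower marked share on the X remained among high CpG promoters (odds ratio 0.314, 95% interval 0.225 to 0.448), which argues against CpG content as the whole cause. It also remained outside gene families and predicted genes, with 203 of 228 promoters marked on the X and 8227 of 8598 on the autosomes (odds ratio 0.366, 95% interval 0.237 to 0.587). Marked high CpG promoters of the X had a lower median enrichment value, 9.01 against 14.4, a difference of -5.37 (p = 0.0001, permutation test, the smallest possible). A lower median had been written in advance as what a single X in males would give. Both pools also held females, and the test cannot tell this from other features of the X. Beyond this comparison no biological explanation was tested, and the gene content of the X stays open.

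The 4364 replicated peaks that did not overlap both replicate lists had a median enrichment value of 3.34. This lay below the lower quartile of the other replicated peaks, 3.84, as predicted for weak peaks missed in the calling of 1 library. Since overlap between the replicates fell with the enrichment value, low values were likely here whatever the cause. The comparison therefore cannot decide on that explanation. Of the 4364 peaks, 78.8% overlapped replicate 2 alone, 19.2% replicate 1 alone and 1.97% neither. A weaker replicate 1 may thus account for most of them but not for all. The rule behind the replicated list, which is not given in the sources used here, was not tested.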
